A study of Cucumis sativus with 63 samples.

How the data were processed

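RNA was extracted with Trizol from cucumber (Cucumis sativus) hypocotyls, the stem below the seed leaves, and 1 µg of total RNA went into each Illumina TruSeq RNA library, per the labels' protocols. The 63 libraries form 21 groups of 3. One group was sampled at 0 h (ck), and 20 groups were sampled at 6, 12, 24, 48 and 96 h under the codes W, WNAA, WETH and WMJA. The series title names waterlogging, and W is read here as the waterlogged plants. The labels do not spell out the other codes or give doses. NAA is a usual abbreviation of 1-naphthaleneacetic acid, an auxin, and MJA of methyl jasmonate, while ETH can stand for ethephon or ethylene. The genotype label is Zaoer-N at 0 h and Pepino at every later time, so a difference from 0 h cannot be told apart from a difference between those labels or from time itself. No group without waterlogging was sampled after 0 h. Nothing in the labels says that replicates came from separate plants, so p-values measure only the spread between these samples, pooled over all groups.

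The deposited table gives FPKM values (fragments per kilobase of gene and 1e6 reads), per the file headers, for 26245 gene IDs in each of the 63 libraries. Of these IDs, 2999 are of a second series (such as Novel02923), and the rest begin with Csa. The aligner, annotation and genome build are not given in the sources used here. None of the IDs matched a RefSeq table of cucumber genes (0 IDs, also 0 in the Csa form with "_"). The file does not pair IDs with gene names, so genes are given by ID alone. The 35 gene lists fixed before the data were examined (fermentation, hormone pathways, cell wall, tissue markers and others) need product names, had 0 lists with members that could be matched, and were not run.

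The deposited FPKM values held whole reads. In 24810 genes above 0 in any library, 100.0% gave whole reads in every library at a tolerance of 0.001 of a read, with 1 total per library and 1 whole length per gene. The recovered reads summed to the recovered total within 133 reads in every library. Totals ran from 15.82 to 28.21 M reads (M, 1e6). A gene of the median length, 1304 bases, with 3 reads would stand at 0.145 FPKM in the library with the lowest total and at 0.0815 FPKM in the one with the highest. On simulated data with 20000 genes and 12 libraries the recovery gave every read count right for 99.95% of the 14904 genes with reads in at least 3 libraries, with a largest error of 0.0% in the totals. Pairs of replicates differed by far more than sampling noise: over genes with at least 20 reads, chi-square per gene was 29.2 to 518 in the 63 pairs, and every library counted as 1 replicate.

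FPKM values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend). A log2 difference on this scale understates the change of low genes. Genes with at least 1 FPKM in at least 3 libraries were kept, which left 20718 genes. One model with a mean for each of the 21 groups was fitted to all 63 libraries, leaving 42 residual degrees of freedom. Tests were two-sided, adjusted by Benjamini-Hochberg over the genes of each comparison. A gene was called at an adjusted p below 0.05 and a log2 difference of at least 1 either way. Comparisons were W with 0 h, each compound with W at the same time, the average of these over the 5 times, W at 96 h with W at 6 h, and the compounds with each other. A moderated F test asked whether a compound's difference from W varied over the 5 times. On simulated data for NAA against W at 6 h, over 20718 genes, limma called 76.1% of the 67 genes changed by log2 1.5, 91.0% of the 67 changed by 2.0 and 93.9% of the 66 changed by 3.0. It also called 9 unchanged genes. The changed genes were drawn from those at 5 FPKM or more in W at 6 h, with normal noise of 1 SD per gene in all groups. The real groups varied unequally, with weights from 0.24 (MJA at 96 h) to 2.34 (ETH at 6 h). These shares may therefore not hold for lower genes or for the real groups. Each p-value also rests on 1 spread per gene pooled over all groups. That spread is too small for groups of low weight, such as MJA at 6, 12 and 24 h (0.52, 0.52 and 0.5) and at 96 h.

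The genes named follow a rule fixed before the data were examined. That rule asked for genes with product names and members of the gene lists, and otherwise for IDs, at most 2 up and 2 down per comparison. Named are therefore the 2 called genes with the largest rise and the 2 with the largest fall, among genes with a mean of at least 5 FPKM on the higher side. This was done for W against 0 h and each compound against W, averaged over times, and for W at 96 h against 6 h. The 3 direct comparisons of compounds were not named in the rule, and its extension to them was chosen after the data had been examined. Genes outside this rule are marked where they appear. Alternatives were another pseudocount (0.1), no filter, a filter of 5 FPKM, quantile normalization, a median-of-ratios factor per library, the replicate number as a block, a fit of only the groups compared, no minimum on the fold, and leaving out each library in turn. Alternatives chosen after seeing the data were limma voom on the recovered reads, a replicate block within 1 time, leaving out 3 libraries in doubt, weights per group or per library, and leaving out each library in turn from the F tests of named genes.

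The labels number the replicates 1 to 3 in every group, and nothing says that a number marks a shared plant, batch or day. Of 21 comparisons checked, 2 had a correlation of deviations from the group means over 0.1 in all 3 pairs of same-numbered libraries. These were NAA against W at 24 h (r = 0.64, 0.26 and 0.50) and MJA against W at 48 h (r = 0.15, 0.36 and 0.26), across genes, which are not independent replicates. The mean r was 0.012 for libraries of the same number in other groups and -0.006 for those of other numbers. A block for the replicate number was therefore run as an alternative, over all groups and within 1 time. Numbers were computed with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 as well, and plots were drawn with matplotlib 3.10.9.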

Results

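Transcript levels were measured in cucumber hypocotyls before waterlogging and over 96 h of it, alone (W) or with 1 of 3 compounds, coded NAA, ETH and MJA. Each of the 21 groups held 3 libraries. Library totals were 21.58 to 24.14 M reads (M, 1e6) at 0 h, 21.40 to 26.91 M at 6 h and 15.82 to 28.21 M later. Mean totals were close between treatments, at 19.74 M for W, 19.91 M for NAA, 20.34 M for ETH and 18.75 M for MJA. In a principal component analysis, PC1 held 35.7% of the variance and PC2 14.9%. All 15 MJA libraries lay above 0 on PC1, from 8.0 to 203.5, as did some libraries of the other treatments at 48 and 96 h, such as W 1 to 3 of 48 h (29.2, 7.4 and 82.4) and W 1 of 96 h (47.6). Replicates 3 at 0 h, 2 of MJA at 12 h and 2 of MJA at 96 h lay farthest from their group means, with SDs of their deviations of 0.63, 0.61 and 0.85 on the log2 scale.

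**Figure D1:**
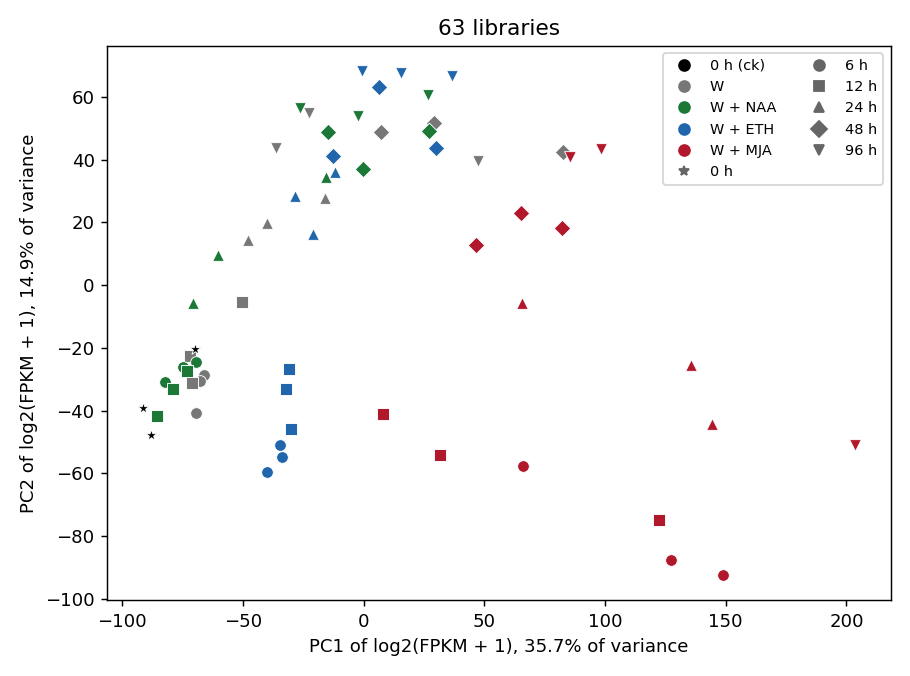
Principal components of the 63 libraries on log2(FPKM + 1), with PC1 (35.7% of variance) on the x axis and PC2 (14.9%) on the y axis. Each point is 1 library, colours give the treatment and shapes the time, and MJA libraries reach up to 203.5 on PC1.

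The first comparison asks which genes differ in waterlogged hypocotyls from those at 0 h. Csa5G285030 rose from 0.998 ± 0.520 FPKM at 0 h to 72.5 ± 1.06 at 6 h and 10600 ± 5780 at 48 h in W (SD, n = 3). Its level at 96 h in W was uneven, with replicates at 10100, 84.7 and 148 FPKM. Csa2G368260 rose from 2.18 ± 0.436 FPKM to 1830 ± 1080 at 24 h. Csa3G046230 fell from 153 ± 96.8 FPKM at 0 h (97.3 without replicate 3) to between 0.226 and 3.37 at the later times, and Csa3G078800 fell from 599 ± 222 to a lowest mean of 1.78 ± 0.890 at 24 h. All 4 passed the test at each of the 5 times and held their direction in all 15 W libraries.

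Averaged over the 5 times, the log2 difference of W from 0 h was 7.97 (SE 1.05) for Csa5G285030 and 7.27 (SE 0.77) for Csa2G368260, with limma Benjamini-Hochberg adjusted p of 6.49e-08 and 4.60e-10. For Csa3G046230 and Csa3G078800 it was -6.05 (SE 0.59) and -5.87 (SE 0.39), with limma Benjamini-Hochberg adjusted p of 4.69e-11 and 6.28e-16. Genes called in W against 0 h numbered 3540 at 6 h, 3157 at 12 h, 4273 at 24 h, 6150 at 48 h and 4583 at 96 h. At 48 h 2103 were higher and 4047 lower. The averaged difference called 3821 genes, 1085 higher and 2736 lower, and the median of all genes was shifted by -0.14. With quantile normalization the averaged split was 1588 higher and 1977 lower around a median of 0.04. At 6 h 886 were higher and 2654 lower, against 46.9% higher with quantile normalization and 40.9% with median-of-ratios scaling. The share higher was 35.4% against 47.6% with quantile normalization at 12 h and 34.2% against 47.4% at 48 h. At 96 h it was 27.4%, against 46.9% with quantile normalization and 39.9% with median-of-ratios scaling. The 0 h group carries another genotype label than every later group, so this comparison does not isolate waterlogging. At 96 h a fit of only the 2 groups called 2660 genes.

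Calls recurred between times: 210 genes were higher and 880 lower at all 5 times, where independent lists would share 0.0234 and 1.04. The 5 comparisons share the 0 h libraries, so their lists are not independent. Within waterlogging, W at 96 h was compared with W at 6 h, which removes the genotype label. Csa1G188670 fell from 1160 ± 177 FPKM at 6 h to 0.0902, 1.59 and 1.98 in the 3 libraries at 96 h, and Csa1G188680 from 1360 ± 287 to 9.20 ± 12.4 (SD, n = 3). Csa4G017070 rose from 0.063 ± 0.0548 to 499 ± 605 FPKM and Csa4G000860 from 2.14 ± 1.36 to 1810 ± 2410. Without W 1 of 96 h these last means were 152 and 430, and that of Csa1G188680 was 2.14 without W 2. The log2 differences were -9.14 (SE 1.36) for Csa1G188670, -8.02 (SE 1.38) for Csa1G188680, 8.05 (SE 0.91) for Csa4G017070 and 7.90 (SE 1.29) for Csa4G000860, with limma Benjamini-Hochberg adjusted p of 2.08e-06, 2.26e-05, 7.02e-09 and 1.05e-05. In all 3134 genes were called, 1364 higher and 1770 lower at 96 h. No group without waterlogging was sampled at these times, so time and waterlogging go together.

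**Figure D2:**
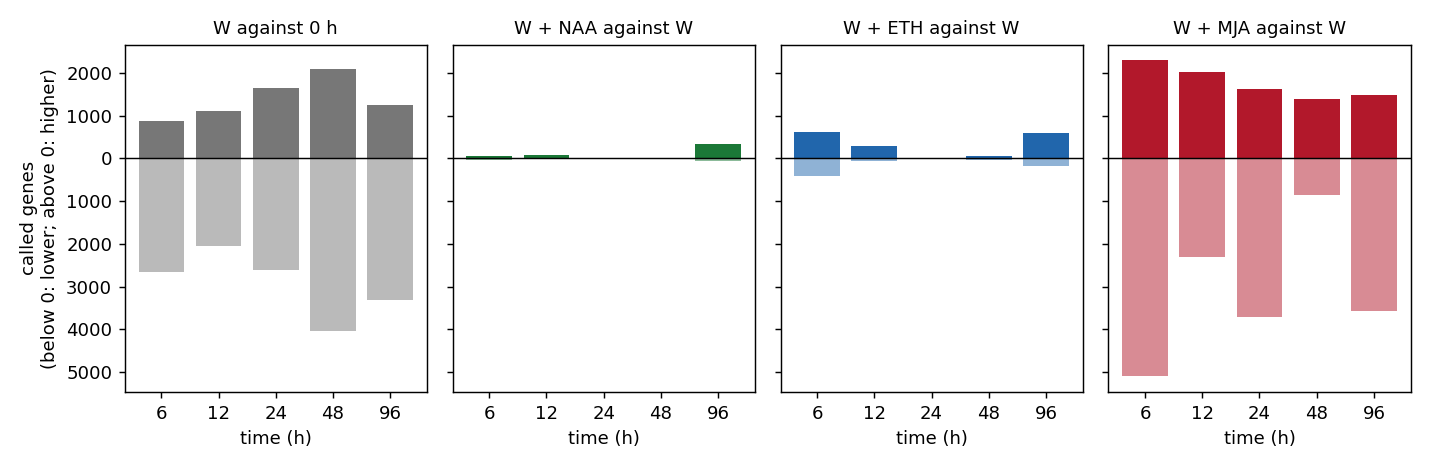
Called genes (y axis, number; bars above 0 are higher, paler bars below 0 lower) at each time (x axis, h) for W against 0 h and for each compound against W at the same time. MJA calls run from 2236 to 7400 genes, ETH from 7 to 1041 and NAA from 1 to 404.

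Averaged over the 5 times, 91 genes passed the test between NAA and W. Csa5G550240 was at 13.6 ± 10.9 FPKM with NAA and 0.477 ± 0.169 in W at 6 h, 21.8 ± 16.8 and 0.815 ± 0.619 at 12 h, and 11.6 ± 1.39 and 0.825 ± 0.194 at 48 h (SD, n = 3). Csa2G420990 was at 1.24 ± 1.17 with NAA and 20.9 ± 3.77 in W at 6 h, and at 4.61 ± 3.24 and 150 ± 86.1 at 48 h. Csa1G032450 was at 12.9 ± 6.00 with NAA and 128 ± 26.0 in W at 6 h. Novel02923 was at 50.6 ± 17.4 with NAA and 7.93 ± 8.02 in W at 12 h.

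Averaged over times, Csa5G550240 rose by 2.35 (SE 0.31) and Novel02923 by 2.15 (SE 0.42) on the log2 scale, with limma Benjamini-Hochberg adjusted p of 8.69e-06 and 0.00339. Csa2G420990 fell by 2.83 (SE 0.41) and Csa1G032450 fell by 2.13 (SE 0.36), with limma Benjamini-Hochberg adjusted p of 4.83e-05 and 0.000686. At single times Csa5G550240 passed at 6 and 12 h, Csa2G420990 at 12 and 48 h and Csa1G032450 at 6 h, while Novel02923 passed at none. In the F test for a difference between times their limma Benjamini-Hochberg adjusted p were 0.586, 0.226, 0.410 and 0.382.

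Called genes numbered 86 at 6 h, 94 at 12 h, 1 at 24 h, 4 at 48 h and 404 at 96 h, and 91 on average, 52 higher and 39 lower. With quantile normalization the averaged split was 46 and 49, and with median-of-ratios scaling 46 and 47, so the larger side turned. The 1 gene at 24 h was Csa6G493310, at 15.7 ± 11.6 FPKM against 1.54 ± 1.46. Those at 48 h were Csa7G446930, Csa1G422470, Csa1G423270 and Csa2G420990. All but Csa2G420990 fall outside the naming rule and were chosen after their values were seen. Without W 2, W 3, NAA 1 or NAA 2 the count at 6 h was 28, 34, 33 or 27. At 12 h it was 39 and 57 without W 1 and W 2, and 28, 16 and 143 without NAA 1, 2 and 3. At 24 h it was 126 without NAA 1, and 0 in limma without W 2, W 3 or NAA 3 (692, 860 and 246 genes at an unadjusted p below 0.05). At 48 h it was 7 without W 1 or W 2, 19 and 9 without NAA 2 and NAA 3, and 0 in limma without W 3 or NAA 1 (1006 and 1118 at an unadjusted p below 0.05). At 96 h it was 60, 247 and 804 without W 1, 2 and 3, and 169 without NAA 3. The averaged count was 58 without W 2 of 6 h, 60 without NAA 1 of 12 h, 59 without W 1 of 24 h, 179, 59 and 50 without NAA 1, 2 and 3 of 24 h, and 59 without W 1 of 96 h. In fits of only the 2 groups limma called 0 genes at 12, 24, 48 and 96 h (3991, 972, 2812 and 1819 at an unadjusted p below 0.05). The main fit had 2234, 860, 1820 and 2922 genes at that p, so the number fell only at 96 h. The calls were lost without the other groups in the fit. Group weights, which allow each group its own spread, called 372 genes at 12 h and 131 at 48 h, in place of 94 and 4. This argues against a larger spread of these groups as the cause at 12 and 48 h. At 24 h, with 3 in place of 1, and at 96 h, with 208 in place of 404, larger spread stays open. Fewer degrees of freedom were not tested as a cause. At 24 h limma also called 0 with quantile normalization, median-of-ratios scaling and voom (1143, 947 and 653 at an unadjusted p below 0.05). A pseudocount of 0.1 gave 33, 33 and 7 at 6, 12 and 48 h, 155 on average and in limma 0 at 24 h (640 at an unadjusted p below 0.05). Voom gave 57 and 36 at 6 and 12 h and in limma 0 at 48 h (1664 at an unadjusted p below 0.05). A filter of 5 FPKM gave 54 at 12 h, and no filter 2 and 13 at 24 and 48 h. A replicate block within 1 time gave 100 at 48 h and in limma 0 at 12, 24 and 96 h (2809, 1412 and 1447 at an unadjusted p below 0.05). Group weights gave 545, 372, 3, 131 and 208 by time, and library weights, whose fit stopped before convergence, 887, 737, 219, 878 and 842, and 158 on average. Higher calls were 62.8% at 6 h, against 42.2% with quantile normalization and 49.0% with median-of-ratios scaling. They were 94.7% at 12 h, against 81.5% with quantile normalization, and at 48 h 2 genes were higher and 2 lower, against 4 and 2 with quantile normalization.

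Of the 5 times, 6 and 96 h had the most genes called for ETH against W in the fit of all groups. With only the 2 groups compared, limma called 0 genes at 96 h (2965 at an unadjusted p below 0.05) and 571 at 12 h. Csa7G037550 was at 47.9 ± 15.2 FPKM with ETH and 0.0276 ± 0.0477 in W at 6 h, and at 204 ± 111 and 0.431 ± 0.342 at 12 h (SD, n = 3). By 96 h it was at 43.3 ± 59.5 and 27.1 ± 25.6, which did not pass the test. Csa3G141900 was listed at 0 in all 3 W libraries at 6 h and stood at 18.7 ± 1.89 with ETH, which did not pass. At 12 h it rose to 609 ± 524 against 0.790 ± 0.537. At 48 h its order was turned, with 188 ± 140 FPKM in ETH and 1150 ± 1380 in W, again within the spread. Novel00133 was at 12.8 ± 1.80 with ETH and 78.7 ± 43.0 in W at 6 h, and Csa6G460000 at 0.429 ± 0.470 and 36.3 ± 37.5 at 96 h; neither passed at a single time.

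Averaged over times, the log2 difference of ETH from W was 3.48 (SE 0.37) for Csa7G037550 and 3.86 (SE 0.72) for Csa3G141900, with limma Benjamini-Hochberg adjusted p of 5.98e-09 and 0.000367. It was -1.85 (SE 0.46) for Novel00133 and -2.01 (SE 0.65) for Csa6G460000, with limma Benjamini-Hochberg adjusted p of 0.00671 and 0.0383. The call of Csa6G460000 was lost on leaving out any of 17 libraries in turn and with voom (log2 difference -2.68, limma Benjamini-Hochberg adjusted p = 0.0834). Means of Csa3G141900 over times were 802 FPKM with ETH and 733 in W, but 372 without ETH 3 of 96 h and 233 without W 1 of 96 h. Called genes numbered 1041 at 6 h, 369 at 12 h, 7 at 24 h, 86 at 48 h and 778 at 96 h, and 217 on average, 159 higher and 58 lower. In fits of only the groups compared, limma called 1892 genes at 6 h, 571 at 12 h and 2 at 24 h. It called 0 at 48 and 96 h, with 2494 and 2965 at an unadjusted p below 0.05, against 2197 and 4192 in the main fit. The calls at 48 and 96 h were thus lost without the other groups in the fit, for a reason that was not tested. The averaged count was 421 with a pseudocount of 0.1 and 392 with voom. At 24 h 3 genes were called with that pseudocount or a filter of 5 FPKM and 2 with voom, and at 48 h 39 with voom. A replicate block within 1 time gave 1 at 24 h, 156 at 48 h and in limma 0 at 96 h (2261 at an unadjusted p below 0.05). Group weights gave 1999, 1145 and 130 at 6, 12 and 24 h, and library weights, whose fit stopped before convergence, 2184, 1647, 420, 965 and 2415 by time and 369 on average. At 6 h 564 genes were called without W 2 and 573 without ETH 3. At 12 h 157, 187, 172 and 100 were called without W 2, W 3, ETH 2 and ETH 3. At 48 h 53, 23 and 18 were called without W 2, W 3 and ETH 2, and at 96 h 483 and 1287 without W 2 and W 3. Higher calls were 59.8% at 6 h, against 49.1% with median-of-ratios scaling, and 80.5% at 12 h, against 60.4% with quantile normalization and 65.5% with median-of-ratios scaling. At 48 h they were 68.6%, against 52.2% with quantile normalization.

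MJA gave the most called genes of the 3 compounds at each of the 5 times. Csa4G304760 stood at 1680 ± 1200 FPKM with MJA and 0.549 ± 0.0584 in W at 6 h, 705 ± 542 and 0.160 ± 0.0692 at 24 h, and 70.4 ± 45.6 and 19.7 ± 29.9 at 96 h (SD, n = 3). The W libraries at 96 h were at 54.2, 2.59 and 2.19. It passed at every time. Csa3G141900 reached 608 ± 336 FPKM at 6 h and 4000 ± 3890 at 24 h with MJA, against 0 in all W libraries and 3.11 ± 4.57, and did not pass at 48 h. Csa2G352410 fell at every time, from 604 ± 120 in W to 16.7 ± 20.5 with MJA at 6 h and from 28.9 ± 19.3 to 0.167 ± 0.162 at 48 h. Csa3G064230 fell at 12, 24, 48 and 96 h, with 11.9 ± 17.9 against 786 ± 280 at 24 h, and at 6 h was at 32.6 ± 37.9 against 53.7 ± 13.3.

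Averaged over times, the log2 difference of MJA from W was 7.32 (SE 0.35) for Csa4G304760 and 7.40 (SE 0.72) for Csa3G141900, with limma Benjamini-Hochberg adjusted p of 1.96e-21 and 9.01e-12. For Csa3G064230 and Csa2G352410 it was -4.66 (SE 0.49) and -4.46 (SE 0.43), with limma Benjamini-Hochberg adjusted p of 5.84e-11 and 6.47e-12. Called genes numbered 7400 at 6 h, 4328 at 12 h, 5350 at 24 h, 2236 at 48 h and 5053 at 96 h, and 3926 on average, 1414 higher and 2512 lower. The same direction was called at all 5 times for 80 higher and 109 lower genes, where independent lists would share 0.084 and 0.725. Each time had its own libraries, but all times share 1 estimate of spread per gene, so the lists are not fully independent. Across genes, which are not independent replicates, the MJA differences correlated at r = 0.80 between 6 and 12 h and at 0.16 between 48 and 96 h.

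The median of all genes was shifted by -0.18 in MJA against W on average, by -0.33 at 6 h, -0.30 at 24 h and -0.24 at 96 h. With a median-of-ratios factor the averaged split was 1926 higher and 1832 lower, and with quantile normalization 1670 and 1811. Higher calls moved from 31.0% to 51.2% and 45.7% at 6 h, from 30.4% to 49.6% and 47.5% at 24 h and from 29.4% to 45.8% and 48.1% at 96 h, in that order of scalings. At 96 h the count was 2677 without MJA replicate 2 and 2951 without the 3 libraries in doubt. In a limma fit of only the 2 groups it was 1 (5043 at an unadjusted p below 0.05, against 10160 in the main fit). The count at 96 h thus depends on the other groups in the fit. It was 764 with a replicate block within that time and 1941 with group weights. The averaged count was 5902 with a pseudocount of 0.1 and 6223 with voom. At 12 h it was 2608 without MJA replicate 2 and 2873 with only the 2 groups, and at 48 h 1428 without MJA replicate 2.

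**Figure D3:**
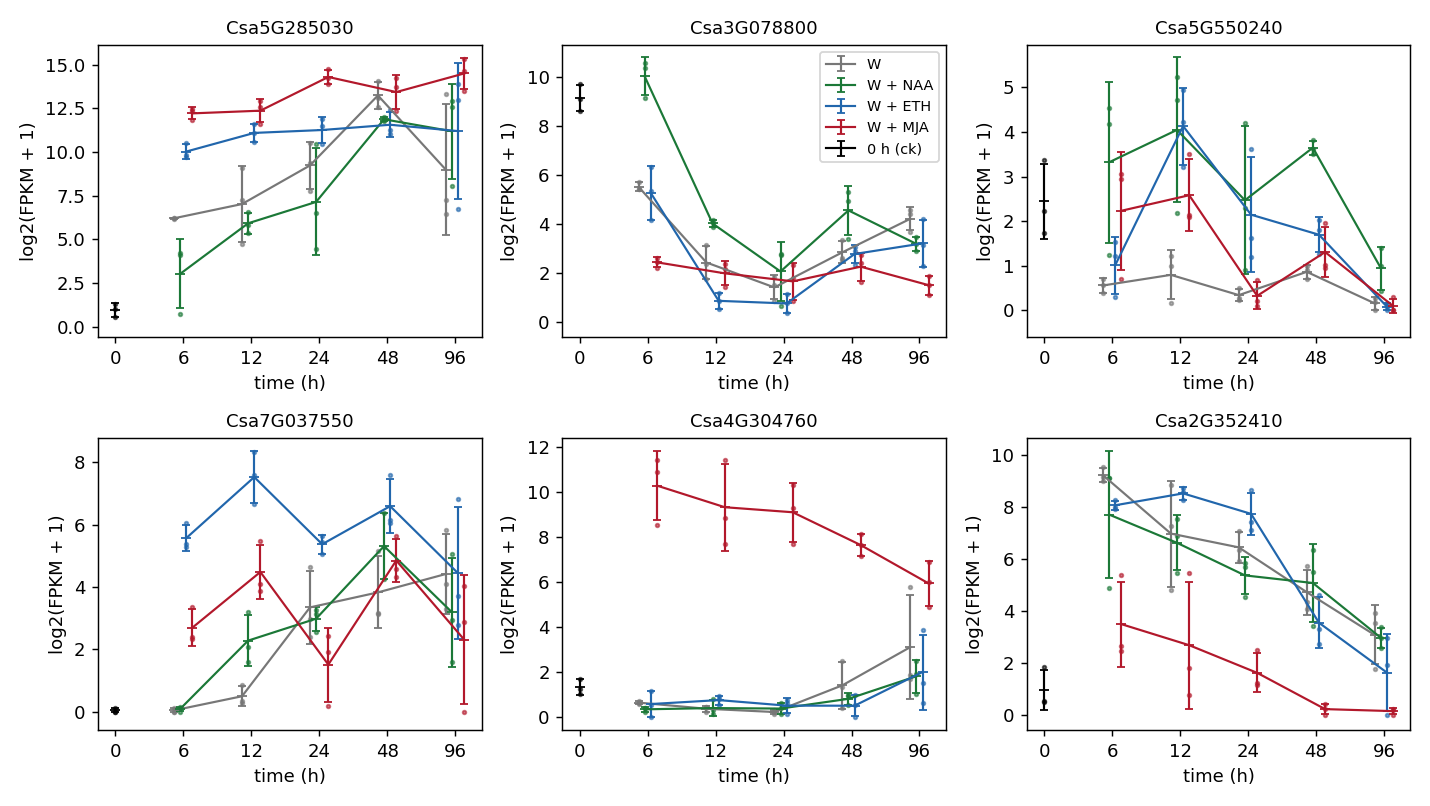
Levels of 6 named genes as log2(FPKM + 1) (y axes, each panel with its own range) at 0 to 96 h (x axes, times evenly spaced). Points are libraries, dashes joined by lines are group means and bars the SD of 3 libraries; Csa4G304760 has a log2 difference of MJA from W of 7.32 averaged over times.

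Direct comparisons asked how the compounds differed from each other; their doses are not in the labels. Csa4G304760 averaged 0.888 FPKM with NAA and 1.48 with ETH, against 764 with MJA. Novel01107 was at 10.3 FPKM with NAA and 3700 with MJA, and Csa4G064650 at 8.67 with ETH and 1840 with MJA. Csa1G188680 and Csa1G188670 stood at 787 and 807 FPKM with NAA and 57.1 and 48.3 with MJA. Csa3G064230 was at 748 FPKM with ETH and 26.2 with MJA, and Csa1G042340 at 179 and 10.3. Between NAA and ETH, Novel00395 was at 11.5 and 0.288 FPKM and Novel00133 at 31.4 and 6.99, while Csa5G027950 was at 276 and 509 and Csa3G141900 at 442 and 802. At 48 h the order of the last 2 was turned, with 818 and 371 FPKM for Csa5G027950 and 553 and 188 for Csa3G141900. FPKM means weigh the highest libraries most, unlike averaged log2 differences. Some of these means over times rest on 1 library. Without MJA 2 of 96 h that of Novel01107 was 1720 with MJA, and without MJA 1 of 12 h those of Csa1G188680, Csa1G188670 and Csa1G042340 were 26.7, 29 and 6.79. Without ETH 3 of 96 h Csa4G304760 was at 0.662 and Csa3G141900 at 372 with ETH, and without NAA 2 of 96 h Csa3G141900 was at 270 with NAA.

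The log2 differences of NAA from MJA were -7.73 (SE 0.35) for Csa4G304760, -7.46 (SE 0.83) for Novel01107, 5.15 (SE 0.62) for Csa1G188680 and 5.02 (SE 0.61) for Csa1G188670. Those of ETH from MJA were -7.61 (SE 0.35) for Csa4G304760, -7.02 (SE 0.35) for Csa4G064650, 5.39 (SE 0.49) for Csa3G064230 and 4.27 (SE 0.46) for Csa1G042340. Those of NAA from ETH were 2.40 (SE 0.29) for Novel00395, 2.35 (SE 0.46) for Novel00133, -3.31 (SE 0.75) for Csa5G027950 and -3.30 (SE 0.72) for Csa3G141900. The largest limma Benjamini-Hochberg adjusted p among the 12 was 0.00257, for Csa5G027950. Averaged over times, 382 genes differed between NAA and ETH, 209 higher with NAA and 173 lower. Between NAA and MJA 4473 differed, 3061 higher with NAA and 1412 lower, or 54.5% and 53.8% higher with quantile and median-of-ratios scaling in place of 68.4%. Between ETH and MJA 3291 differed, 2163 higher with ETH and 1128 lower, or 50.3% and 46.3% higher in place of 65.7%. Median shifts were 0.24 and 0.22 in these last comparisons. With voom the 3 counts were 728, 6862 and 5526, and with a pseudocount of 0.1 NAA against ETH gave 721 and ETH against MJA 5209.

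ETH and MJA, both set against W, shared 84 higher and 38 lower calls, where independent lists would share 10.9 and 7.0, and 6 genes were called in opposite directions. NAA and MJA shared 5 higher and 13 lower calls and had 28 in opposite directions, where independent lists would share 3.5 and 4.7. NAA and ETH shared 3 higher and 13 lower, where independent lists would share 0.4 and 0.1, and had 1 in opposite directions. The covariance of the averaged differences across genes was 0.1249 for ETH and MJA, -0.0189 for NAA and MJA and 0.0204 for NAA and ETH, against 0.0154, 0.0155 and 0.0153 simulated for unchanged groups that share the W libraries. The correlations were 0.45, -0.08 and 0.26, against 0.50 simulated. The W libraries are shared by these comparisons, so their lists are not independent.

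The difference from W varied over the 5 times in 254 genes for NAA, 1450 for ETH and 11997 for MJA by the moderated F test of limma. With W and compound libraries mixed within each time, the same test called up to 429, 663 and 10529 genes. Such mixing also turns a steady difference into one that varies, so it cannot tell whether chance accounts for these counts. Among the genes named for a compound's own difference from W, it varied for Csa7G037550 and Csa3G141900 with ETH (limma Benjamini-Hochberg adjusted p = 0.000582 and 0.0307) and for Csa4G304760 and Csa3G064230 with MJA (1.15e-05 and 0.0195). Of genes named in other comparisons, Csa3G078800 varied with NAA (limma Benjamini-Hochberg adjusted p = 0.000384), and Csa2G420990 and Csa4G017070 with ETH (0.0396 and 0.0380). With MJA, Csa2G420990, Csa4G064650, Csa7G037550, Csa3G078800, Csa4G000860, Novel02923 and Novel00133 varied too (limma Benjamini-Hochberg adjusted p = 4.54e-10, 2.85e-06, 6.21e-05, 0.000268, 0.00281, 0.00397 and 0.00901). So did Csa5G027950, Novel00395, Csa2G368260, Csa5G285030 and Csa1G032450 with MJA (limma Benjamini-Hochberg adjusted p = 0.0164, 0.0367, 0.0372, 0.0432 and 0.0453). The log2 difference of Csa7G037550 went from 7.04 (SE 0.83) at 12 h to 0.02 (SE 0.83) at 96 h. That of Csa4G304760 went from 9.66 (SE 0.77) at 6 h to 2.84 (SE 0.77) at 96 h, or to 4.18 (SE 0.75) without W 1 of 96 h, where the F test still passed (limma Benjamini-Hochberg adjusted p = 7.66e-05). Leaving out each of 30 libraries in turn ended the F test call of Csa3G141900 with ETH in 5 cases and of Csa3G064230 with MJA in 1. It ended those of Csa2G420990 and Csa4G017070 with ETH in 13 and 10, and with MJA those of Csa1G032450, Csa5G285030, Csa2G368260, Novel00395 and Csa5G027950 in 20, 14, 8, 7 and 2. The count for NAA was 590 without NAA 1 of 24 h, 41, 43 and 765 without W 1, 2 and 3 of 96 h, and 143 and 40 without NAA 1 and 3 of 96 h. That for ETH was 833, 894 and 2343 without W 1, 2 and 3 of 96 h, and 862 without ETH 1 of 96 h. With only the groups compared the counts were 97 for NAA and 4324 for ETH, with group weights 1193 and 7133, and with quantile normalization 564 and 2325. Median-of-ratios scaling gave 441 for NAA, and library weights, whose fit stopped before convergence, 6288 and 13787.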

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

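The tests of named genes between times with 1 library left out, of shared handling by replicate number, of gene length, of places along the MJA difference and of all other splits of the libraries were chosen after the result was seen. The difference of a compound from W varied between times, by the F test of limma with Benjamini-Hochberg adjustment, for Csa3G141900 with ETH (adjusted p = 0.0307) and Csa7G037550 with ETH (adjusted p = 0.000582). By the same limma test it varied for Csa4G304760 with MJA (Benjamini-Hochberg adjusted p = 1.15e-05) and Csa3G064230 with MJA (adjusted p = 0.0195). Of genes named in other comparisons, Csa3G078800 passed this limma Benjamini-Hochberg test with NAA (0.000384), and Csa2G420990 and Csa4G017070 with ETH (0.0396 and 0.0380). With MJA it passed for Csa2G420990 (4.54e-10), Csa4G064650 (2.85e-06), Csa7G037550 (6.21e-05), Csa3G078800 (0.000268), Csa4G000860 (0.00281), Novel02923 (0.00397) and Novel00133 (0.00901). It also passed with MJA for Csa5G027950 (0.0164), Novel00395 (0.0367), Csa2G368260 (0.0372), Csa5G285030 (0.0432) and Csa1G032450 (0.0453). Of these genes, the calls of Csa3G141900, Csa2G420990 and Csa4G017070 with ETH ended on leaving out 5, 13 and 10 of 30 libraries in turn. With MJA those of Csa3G064230, Csa1G032450, Csa5G285030, Csa2G368260, Novel00395 and Csa5G027950 ended in 1, 20, 14, 8, 7 and 2 cases. The same test passed for 254 genes with NAA, 1450 with ETH and 11997 with MJA. Splits of the libraries, given below, cannot tell whether chance accounts for these counts. Groups of 3 libraries were not tested for outliers.

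NAA replicate 1 at 24 h matched W replicate 1 of that time at r = 0.985 across genes and its own group at 0.892 and 0.932. A wrong label stays possible: on the 58 genes called for the NAA difference averaged over the other 4 times, fitted without the 24 h libraries, it scored -0.07, or -0.44 relative to the highest W library, while NAA 2 and 3 scored 1.68 and 2.09. Handling shared by replicate number could also account for it, since same-numbered libraries of the other 5 pairs of 24 h groups correlated at a mean r of 0.19 (SE 0.04). All of these pairs but ETH with MJA hold W or NAA libraries, so the test is not independent of the match. The SE takes 15 library pairs as independent, although each library enters more than 1 of them. Neither is excluded, a weaker response of that sample stays open too, and no biological explanation was tested. Without this library 126 genes were called for NAA at 24 h, in place of 1. Other libraries also matched another group best. Among them were W 1, W 3 and all NAA and ETH libraries at 96 h, and all ETH libraries at 48 h. MJA 2 of 12 h and MJA 2 of 96 h matched MJA libraries of other times best, at r = 0.943 and 0.880.

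The median gene was lower with MJA than with W by a log2 difference of -0.18. Thinning every library to 15.82 M reads (M, 1e6) left 99.1% of the shift. FPKM values are already divided by the total, so thinning could hardly move the shift and adds little on depth. Mean totals were 19.74 M for W and 18.75 M for MJA. Taking the 100 highest genes out of each total left 93.3%, which argues against a few abundant genes as the cause. The shift was -0.14 in the shortest 25% of genes and -0.23 in the longest 25%. It was thus larger in long genes but present in both, which argues only against gene length as the sole cause. A single scale factor per library stays open. Shifts in 4 classes by level of the 14025 genes with a mean of at least 5 FPKM ran from -0.28 to -0.16, a range of 0.12. Lower genes were not in these classes. A scaling difference and a broad fall of transcripts with MJA cannot be told apart here.

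MJA libraries of 1 group lay apart along the MJA difference, with places from -0.41 to 0.54 (SD 0.36, 15 libraries) against -0.20 to 0.36 for W (SD 0.18, 15 libraries). Their place had r = 0.28 with total reads (95% interval -0.39 to 0.75, p = 0.372 by exact permutation within groups, rho = 0.25, and 0.05 without the 2 farthest). With the share of reads in the top 10 genes r was -0.46 (95% interval -0.83 to 0.19, p = 0.184, rho = -0.43, and -0.21 without the 2 farthest). After Benjamini-Hochberg adjustment of these 2 permutation tests, not limma, p was 0.372 and 0.368. Both intervals are too wide to decide, and no biological explanation was tested.

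The libraries of 2 groups of 3 make 10 splits, too few for a share under 0.05. In W against 0 h the real split called 3540, 3157, 4273, 6150 and 4583 genes at 6, 12, 24, 48 and 96 h, and the highest other 197, 245, 347, 738 and 875 (1 of 10 as large at each time). For W at 96 h against 6 h these were 3134 and 527 (1 of 10). For ETH they were 1041, 369, 7, 86 and 778, and 1, 31, 2, 30 and 606 (1 of 10 at each time). For MJA they were 7400, 4328, 5350, 2236 and 5053, and 1903, 294, 1166, 27 and 2973 (1 of 10 at each time). For NAA they were 86, 94, 1, 4 and 404, and 1, 3, 108, 31 and 292, with 1, 1, 6, 4 and 1 of 10 as large. The split with 108 genes at 24 h puts NAA 1 with W 1 and W 2, and that with 31 at 48 h puts NAA 2 with W 1 and W 2, so the larger counts come with a structure of the samples, whose cause was not tested at 48 h. Among the 4 splits at 24 h that part all 3 number pairs, 3 were as large as the real one for NAA, and the highest other called 1; at 48 h 1 of 4 was as large for MJA, and the highest other called 9.

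With 100 splits each, chance can be excluded for the averaged differences from W of NAA (91 genes, highest other 3), ETH (217 and 9) and MJA (3926 and 2420), and for W against 0 h (3821 and 2919), with 1 of 100 as large in each. The same held for NAA against ETH (382 and 77), NAA against MJA (4473 and 3107) and ETH against MJA (3291 and 1424), with 1 of 100. A share of 1 of 100 is the lowest that 100 splits can give, and it takes the libraries as independent samples. For the differences between times the real split called 1450 genes with ETH and the highest other 663. With MJA these were 11997 and 10529, with 1 of 100 as large for each of these 2 compounds. With NAA they were 254 and 429, with 2 of 100 as large, a share not adjusted for the other tests of splits. Mixing W and compound libraries within each time also turns a steady difference into one that varies over times. These splits therefore cannot tell whether chance accounts for the counts of differences between times. With NAA the count also ran from 40 to 765 on leaving out 1 library (without NAA 3 and W 3 of 96 h).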

How the results depend on the processing

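The tests with voom, the block within 1 time, the weights and the libraries left out together were chosen after the result was seen. The 32 results of named genes held their direction in all 1152 alternatives, and 18 of these, all for Csa6G460000 with ETH, ended its call. The named genes were picked as the largest differences in the same libraries, so a turn of direction was unlikely from the start. Scaling by quantile or median-of-ratios held the count of calls within 1.5 times in all but the cases given here. The cause was not tested for any change below except where fewer libraries or no minimum on the fold make it. For NAA with only the groups compared, the values on larger spread are given above. The 35 gene lists were not run. With 3 reads, a gene of 1304 bases stands at 0.145 FPKM at the lowest depth, so lower levels are not resolved.

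With no fold minimum, counts for W against 0 h were 6509, 5924, 7745, 9996 and 8096 by time and 9014 averaged, and 5332 for W at 96 h against 6 h. They were 608 for NAA at 96 h and 545 averaged, 2097, 578 and 1578 for ETH at 6, 12 and 96 h and 2134 averaged, and 11387, 7509, 8861, 4405 and 8482 for MJA by time and 13920 averaged. NAA against ETH, NAA against MJA and ETH against MJA gave 2343, 14512 and 13337.

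With only the groups compared, W against 0 h at 96 h gave 2660, ETH 1892, 571 and 2 at 6, 12 and 24 h, and MJA 2873 at 12 h and 1 at 96 h. Differences between times gave 97 for NAA and 4324 for ETH. Limma called 0 for NAA at 12, 24, 48 and 96 h (3991, 972, 2812 and 1819 at an unadjusted p below 0.05) and 0 for ETH at 48 and 96 h (2494 and 2965).

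A pseudocount of 0.1 gave NAA 33, 33 and 7 at 6, 12 and 48 h and 155 averaged, and in limma 0 at 24 h (640 at an unadjusted p below 0.05). It gave ETH 3 at 24 h and 421 averaged, MJA 5902 averaged, NAA against ETH 721 and ETH against MJA 5209. A filter of 5 FPKM gave 54 for NAA at 12 h and 3 for ETH at 24 h, and no filter 2 and 13 for NAA at 24 and 48 h. Quantile normalization and median-of-ratios scaling gave 0 for NAA at 24 h in limma (1143 and 947 at an unadjusted p below 0.05). For differences between times quantile normalization gave 564 with NAA and 2325 with ETH, and median-of-ratios scaling 441 with NAA.

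Voom on recovered reads gave NAA 57 and 36 at 6 and 12 h and in limma 0 at 24 and 48 h (653 and 1664 at an unadjusted p below 0.05). It gave ETH 2 and 39 at 24 and 48 h and 392 averaged, MJA 6223 averaged, and 728, 6862 and 5526 for NAA against ETH, NAA against MJA and ETH against MJA. Without the 3 libraries of SD over 0.6 MJA at 96 h gave 2951.

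The replicate block over all groups held every count within 1.5 times, with 91 for NAA, 214 for ETH and 3926 for MJA averaged, and 1 for NAA at 24 h and 2242 for MJA at 48 h, where numbers pair. This block has 1 effect per number over all groups, so it cannot take up a pairing found at 1 time only. The replicate block within 1 time gave NAA 100 and ETH 156 at 48 h, ETH 1 at 24 h and MJA 764 at 96 h. In limma it gave 0 for NAA at 12, 24 and 96 h (2809, 1412 and 1447 at an unadjusted p below 0.05) and for ETH at 96 h (2261).

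Group weights gave NAA 545, 372, 3, 131 and 208 by time, ETH 1999, 1145 and 130 at 6, 12 and 24 h, MJA 1941 at 96 h, and 1193 and 7133 for NAA and ETH between times. Library weights, whose fit stopped before convergence, gave NAA 887, 737, 219, 878 and 842 by time and 158 averaged. They gave ETH 2184, 1647, 420, 965 and 2415 and 369 averaged, and 6288 and 13787 for NAA and ETH between times.

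Leaving out 1 library in turn, the lone pair being assumed to vary like other groups, gave for W against 0 h 2803 to 3721, 2591 to 3251, 3455 to 4230, 5510 to 6292 and 4120 to 4703 by time, and 3721 to 3912 averaged. W at 96 h against 6 h gave 2356 to 3486. NAA gave 27 to 91, 16 to 143, 0 to 126, 0 to 19 and 60 to 804, and 50 to 179 averaged, with limma calling 692 and 1006 genes at an unadjusted p below 0.05 beside the zeros without W 2 at 24 h and W 3 at 48 h. ETH gave 564 to 863, 100 to 405, 5 to 6, 18 to 83 and 483 to 1287, and 175 to 313 averaged. MJA gave 5988 to 8607, 2608 to 5315, 4242 to 6555, 1428 to 2299 and 2677 to 6412, and 3483 to 4221 averaged. NAA against ETH gave 294 to 516, NAA against MJA 3995 to 4769 and ETH against MJA 2817 to 3627. Differences between times gave 40 to 765 for NAA, 833 to 2343 for ETH and 10567 to 13155 for MJA.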

Other observations

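The comparison of the 2 series of IDs and the counts of genes per library were chosen as tests after the data had been examined. Of the 2095 tested IDs of the second series (such as Novel02923), 7.49% were lower in W than at 0 h on average, against 13.85% of the 18623 Csa IDs (odds ratio 0.50, Fisher test, genes taken as independent, p = 6.69e-17 after Benjamini-Hochberg adjustment, not limma, over 56 tests). On average 5.25% and 5.24% of the same IDs were higher, but at 96 h 9.07% and 5.72% were (odds ratio 1.64, Fisher test with Benjamini-Hochberg adjustment, not limma, p = 7.14e-08). With MJA against W on average they were called less often both higher (4.11% and 7.13%, odds ratio 0.56) and lower (8.74% and 12.51%, odds ratio 0.67), with Fisher p of 2.08e-07 and 8.96e-07 after Benjamini-Hochberg adjustment, not limma. With ETH at 96 h they were called more often both lower (1.91% and 0.80%, odds ratio 2.41) and higher (3.72% and 2.74%, odds ratio 1.37), with p of 2.31e-05 and 0.0304 in the same tests. That list of 778 genes was 0 in limma with only the 2 groups or with a replicate block within that time (2965 and 2261 genes at an unadjusted p below 0.05). The 2 series of IDs were not matched by level in these Fisher tests, and log2(FPKM + 1) understates the change of low genes. Whether level accounts for the differences between the series was not tested. The mean number of genes with at least 1 FPKM was 17240 in W, 17571 with NAA, 17400 with ETH and 16783 with MJA, and 17241, 17575, 17403 and 16778 after thinning to the lowest total. The lowest library, MJA replicate 2 at 96 h, had 14657 such genes.

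Called at any of the 5 times were 576 genes for NAA, 2043 for ETH and 11805 for MJA, of which 564, 1816 and 4924 were called at 1 time. For MJA 1215 genes were higher and 2427 lower at 3 or more times, where independent lists would share 109 and 486. The lists share 1 estimate of spread per gene and are not fully independent. For MJA 677 genes were called in both directions at different times. The differences at 96 h correlated with those at the earlier times at r = -0.01, -0.25, -0.20 and -0.21 for NAA, across genes, which are not independent replicates. Between the earlier times r was 0.27 to 0.58 for NAA. At 96 h against 6, 12, 24 and 48 h it was 0.18, -0.07, 0.19 and -0.20 for ETH, and 0.64, 0.49, 0.70 and 0.16 for MJA.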
